A study of Mus musculus with 30 samples.

How the data were processed

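Total RNA from mouse aorta was measured on 30 one-colour Agilent arrays, 1 array per sample, from wild type (WT) and uMT mice of strain label C57BL/6. The 10 groups of 3 were pre, sham at days 7 and 42, and CaCl2 at days 7 and 42, in each genotype. The labels give the tissue of every sample as abdominal aortic aneurysm, the pre and sham samples included. RNeasy and SV Total RNA kits are both named in the records, and which was used is not settled.

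The deposited spot intensities were made per the file headers with Agilent Feature Extraction 10.7.1.1 (the processing notes name 9.5.1.1), which subtracted background, removed spatial and multiplicative trends and gave dim spots a surrogate value. A matrix of processed intensity values was deposited by the authors as well. Its 30 columns hold 1 set of sorted values on a linear scale, that of quantile normalization, and each column follows its own array (lowest r = 0.979). All 30 columns were used as an alternative. The files name 5 slides and 2 scan days, and coordinates are mm9.

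Each array held 59305 non-control spots of 55681 probes. Intensities of the unflagged spots of a probe were averaged before the log2, 24 probes with a non-uniform or outlier flag on every spot of any array were left out, and 55657 were kept. Names came from the probe's accession in the RefSeq table (27221 probes), a symbol (3581), a synonym (565) or the file alone (24290). The log2 processed signal of each array was centred on its 75th percentile. A probe was kept when it was well above background, by the scanner software, on all 3 arrays of at least 1 group (33224 probes). The brightest kept probe stood for a gene, which gave 23267 names, 16016 of them in the RefSeq table and 6699 with several kept probes. Depth on these arrays is signal over background: 16537 probes were well above it on all 30 arrays and 30351 on at least 15. The highest correlation between 2 arrays was 0.993, no spot was saturated, and the first 2 principal components held 35.3% and 25.7% of the variance.

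Changes were estimated with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 30 arrays (20 residual degrees of freedom), moderated t tests and Benjamini-Hochberg adjustment within each of 15 comparisons at 0.05. The standard errors pool the spread of all groups. Replicate numbers were not treated as pairs, and pairing was an alternative. Where all arrays of the dimmer group were below background, the fold was computed against the larger of each array's value and its lowest signal well above background, and is given as "at least".

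The 28 gene lists were written before the data were examined, as were the comparisons, the main choices and the alternatives not named below as added: B cell, immunoglobulin and plasma cell, T and NK cell, macrophage, neutrophil, mast cell, dendritic cell, contractile smooth muscle, fibroblast, endothelial, collagen and provisional matrix, elastic fibre, matrix protease, chemokine and cytokine, Fc receptor and Syk signalling, complement, interferon-induced, cell cycle, bone and cartilage, white adipocyte, brown adipocyte, skeletal muscle, nerve and Schwann cell, lymph node and lymphatic, pancreas, adrenal cortex, stress and immediate early, and Y chromosome and Xist. A further list, the 70 features described as immunoglobulin chains, was added after the data were seen. Lists were tested with fry (limma), and p values were adjusted over the lists of a comparison. Its directional test asks whether the members moved together one way, and its mixed test whether they moved in either direction. The counts of members are those past the adjusted p over all genes and, beside them, over the list alone. In 41 of 435 pairs of list and comparison the mean, the median and the directional test did not share a sign.

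The genes named are the 8 largest rises and 8 largest falls in each of the 4 comparisons of CaCl2 with sham, and 5 and 5 in the others. Each needed an adjusted p under 0.05, a symbol in the reference tables, all arrays of the higher group well above background and no overlap between groups (for the average over conditions, 1 sign in all 5). Among those added were Ighm, Cd79a, Cd79b, Ms4a1, Syk, Mmp2, Mmp9, Ccl2, Il6 and Eln, and up to 4 members of each list. Some genes that the rule chose are not reported here. The single immunoglobulin features and the second Arsk probe were chosen after their values were seen. Genes with an adjusted p under 0.05 and a CaCl2 response of at least 1 (log2) on average over the genotypes made up a response score per array, and its genotype difference was tested over all 400 exchanges of genotype labels within sham and within CaCl2. With 3 arrays against 3, a permutation test has 10 distinct splits, so its p cannot go below 0.10.

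The alternatives were normexp background correction with offset 50 and quantile normalization, quantile normalization alone, the authors' matrix, no filter, a filter of 15 arrays well above background, the mean of a gene's probes, the compared groups alone, a replicate block, slide as a random or fixed block, arrays within 1 slide, and each array left out in turn. Added after seeing the data were fits of all groups without WT sham day 42 replicate 2, without the 6 arrays on which under 50% of probes were well above background, with a percentile over probes well above background on all arrays, and with the random slide block and without WT sham day 42 replicate 2. The pipeline was tested on 20 simulated data sets for WT CaCl2 against sham at day 7, with 200 changed genes each. Noise had the pooled spread of all groups, without slide effects or correlated genes, so the rates apply to such noise only. Of genes changed by 1 and 2 (log2) 14.2% and 62.4% were called, all with the right sign, and 4.65% of calls (0 to 10.9) were false. Of unchanged lists of 15 genes 4.40% were called at an unadjusted p of 0.05 (0 to 8). The data sets were raised from 1 after it gave over 10% false calls in an early run.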

Results

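Aortic RNA was measured on 30 single-colour expression arrays, 3 in each of 10 groups. Wild type mice (WT) and uMT mice, a line without mature B cells, were sampled before any operation (pre), or 7 or 42 days after CaCl2 or saline (sham) was applied around the abdominal aorta. CaCl2 applied in this way is a model of aortic aneurysm, and the series title names B cells, immunoglobulins and the kinase Syk. Between 36.9% and 62.8% of the probes gave signal well above background on an array. The 75th percentile of signal ran from 36.7 to 480 intensity units. Changes are log2 differences of group means ± the standard error of the fit, with n = 3 arrays in each group unless stated, and levels are log2 signal relative to the array's 75th percentile, mean ± SD. Genes are given with adjusted p values from limma over 23267 gene names, and gene lists with adjusted p values from fry, its test of sets, over the lists in a comparison. "At least" before a fold marks a lower bound used where no array of the dimmer group measured the gene above background.

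WT sham day 42 replicate 2 gave the 36.9%, was the only array on its slide and second scan day, and had r = 0.726 across genes with its group mates. Without it every count of called genes rose, except the 0 genes of the day 7 interaction, so each count is given with and without it. The arrays lay on 5 slides that nearly followed the groups. The CaCl2 and sham arrays of uMT mice shared no slide, and the day 7 CaCl2 and sham arrays of WT mice shared none. The estimated correlation within a slide was 0.782 over all arrays and -0.0687 without that array.

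**Figure D1:**
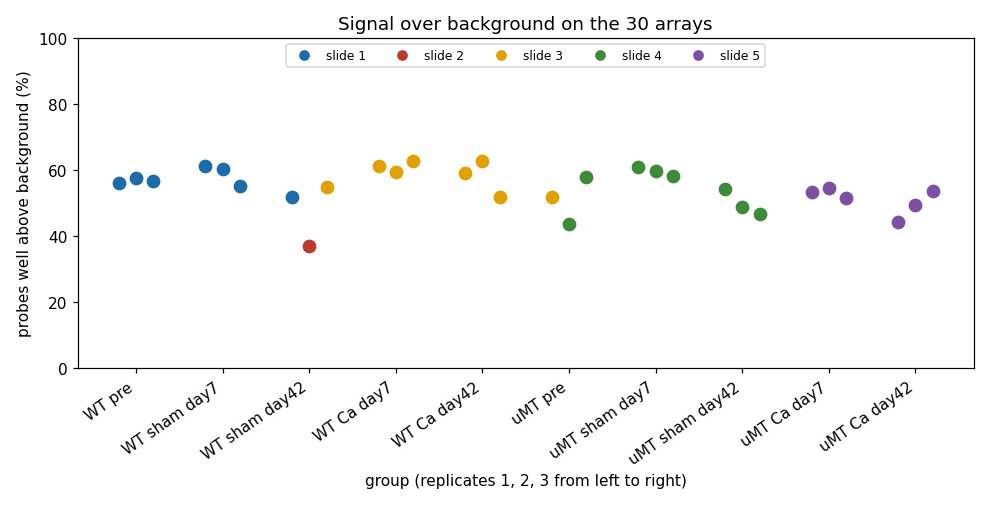
Percentage of probes well above background (y axis) on each of the 30 arrays, by group (x axis) and coloured by slide. WT sham day 42 replicate 2, alone on slide 2, sits at 36.9%, and the other 29 arrays between 43.6% and 62.8%.

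The comparison of uMT with WT mice was averaged over the 5 conditions with n = 15 arrays each. It checked the genotype labels and asked which genes differed on average, a difference that a few conditions can carry. The uMT line carries an altered Ighm gene, whose product is the IgM heavy chain. No probe carries the name Ighm. The feature described as immunoglobulin heavy constant mu (mm9 chromosome 12, 114659630 to 114659689) differed by -0.62 ± 0.25 (adjusted p = 0.186), and gave signal well above background on 14 of 15 uMT arrays. Its position relative to the altered part of the gene is not given in the files, so it checks no label. B cell genes do: Ms4a1, which codes for the surface protein CD20, was well above background on 0 of 15 uMT and 12 of 15 WT arrays. It fell by 2.17 ± 0.39 (adjusted p = 0.00430, at least 1.7-fold lower), and its probe lies at mm9 chromosome 19, 11325367 to 11325426. Cd79a, a signalling chain of the B cell receptor, fell by 0.71 ± 0.17 (adjusted p = 0.0266). Its partner Cd79b differed by -0.95 ± 0.31 (adjusted p = 0.0964). Jchain, which joins the units of secreted IgM and IgA (probe at mm9 chromosome 5, 88949919 to 88949978), fell by 4.34 ± 0.46 (adjusted p = 5.39e-06, at least 6.0-fold).

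Of 13 measured genes of the B cell list, 6 were lower in uMT mice and 9 were lower when adjusted over the list alone, where 1 was higher (fry adjusted p = 3.39e-04). Pou2af1, a B cell transcription coactivator, fell by 2.27 ± 0.25 and Fcrla by 1.52 ± 0.23. Interferon-induced genes were lower in 5 of 13 cases, and in 9 when adjusted over the list alone (fry adjusted p = 0.0360, 3.41e-04 to 0.995 over the alternatives). That call held in 21 of 42 alternatives and was lost under quantile normalization (0.0792), with the authors' values (0.0812), under the stricter filter (0.0540) and with the slide block. They included Irf7, a transcription factor of the interferon response, at -1.06 ± 0.24, and Ifit1 at -1.24 ± 0.30. The immunoglobulin and plasma cell list was lower through 1 of 4 genes by both counts, Jchain (fry adjusted p = 0.00518; 0.444 under the stricter filter). Of 70 features described as immunoglobulin chains, a list put together after the data were seen, 23 were lower and 0 higher (fry adjusted p = 0.00637). Outside these groups, Map1b, which codes for a microtubule-associated protein, was higher in uMT mice by 2.49 ± 0.23 and Nnt, a mitochondrial transhydrogenase, by 1.69 ± 0.12. Serpina3i was higher by 1.75 ± 0.18 and Smo, the signal transducer of the hedgehog pathway, was higher too (adjusted p = 0.0113). Ly6d fell by 1.85 ± 0.29 and Esm1, an endothelial proteoglycan, by 1.36 ± 0.27. Arsk, an arylsulfatase, was higher by 1.77 ± 0.10 at its brightest probe (mm9 chromosome 13, 76199926 to 76199985) but differed by -3.68 ± 0.13 at its other probe (76198809 to 76198868), and neither overlapped between the 15 arrays of each line. Syk did not pass the test, at -0.13 ± 0.21 (adjusted p = 0.830).

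In all, 293 genes were higher and 399 lower in uMT mice, and 2914 and 3122 without WT sham day 42 replicate 2. With slide as a random block 2 genes and none of 28 lists were called, the B cell and the immunoglobulin and plasma cell lists included (adjusted p = 0.995 each). The block without that array called 10631 genes, and the fit without the 6 dim arrays (under 50% of probes well above background) 247. Leaving out any other array in turn gave 346 to 1209 genes, the lowest without WT CaCl2 day 7 replicate 3 and the highest without uMT sham day 42 replicate 1.

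At day 7 after CaCl2 in WT mice, some cytokine and protease genes rose and contractile muscle genes fell against sham arrays on other slides. Mmp13, a collagenase (probe at mm9 chromosome 9, 7282762 to 7282821), rose by 5.65 ± 1.23 (adjusted p = 0.00887), from -4.16 ± 0.23 to 1.49 ± 1.91. The interleukin gene Il1b rose by 4.78 ± 0.81 (adjusted p = 0.00226), the neutrophil chemokine Cxcl5 by 4.82 ± 0.90 and Il6 by 4.39 ± 1.07. Col11a1, a fibrillar collagen of cartilage, rose by 4.70 ± 0.66. Tnn, a tenascin of the matrix, rose as well, and Glycam1, a ligand of L-selectin on vessels of lymph nodes, at least 7.6-fold. Edil3, an integrin ligand, and Cstdc4 rose at least 6.2-fold and 5.0-fold. Sost, an inhibitor of Wnt signalling, fell by 4.99 ± 0.76 (adjusted p = 0.00145), and the organic cation transporter Slc22a2 changed by -4.30 ± 0.83. Inmt and Lmntd1 fell by 3.98 ± 0.86 and 3.80 ± 0.63. The muscle genes Mybpc2 and Vgll2 fell at least 6.8-fold and 9.7-fold. Syk, at 1.34 ± 0.46 (adjusted p = 0.0827), Mmp9, at 4.30 ± 1.36 (0.0577), and Eln, which codes for elastin, at -0.76 ± 0.74 (0.634), did not pass the test.

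Of 15 genes of contractile smooth muscle, 13 fell, and 15 when adjusted over the list alone (fry adjusted p = 0.00376), among them Tpm2 at -2.67 ± 0.47, Mylk at -2.55 ± 0.50 and Cnn1 at -2.69 ± 0.60. Matrix proteases rose in 4 of 16 cases, and 6 when adjusted over the list alone, where 2 fell (adjusted p = 0.00677), with the membrane-type protease Mmp14 at 1.91 ± 0.33 and Adamts4, an aggrecanase, at 2.86 ± 0.67. Chemokines and cytokines rose in 3 of 22 cases, 10 adjusted over the list alone (adjusted p = 0.0120). Fc receptor and Syk signalling genes rose in 5 of 16, 9 adjusted over the list alone (adjusted p = 0.0176), with the kinases Btk at 3.39 ± 0.66 and Fgr at 2.56 ± 0.64. Mast cell proteases fell in 3 of 5 cases by both counts (adjusted p = 0.0234), with Cma1, a chymase, at -3.71 ± 0.73. The lists of lymph node and lymphatic genes (1 of 6, 3 adjusted over the list alone; adjusted p = 5.72e-04), B cells (1 of 13, 4; adjusted p = 0.0120), dendritic cells (1 of 7, 2; adjusted p = 0.0120), neutrophils (1 of 10, 4; adjusted p = 0.0234), T and NK cells (0 of 16, 0; adjusted p = 0.0120) and the cell cycle (0 of 17, 0; adjusted p = 0.0485) were higher. Brown adipocyte genes were lower (1 of 7, 3; adjusted p = 0.0120). The cell cycle call held in 7 of 20 alternatives and was lost under quantile normalization (adjusted p = 0.124), with the authors' values (0.127), with the replicate block (0.0545) and in 5 of 6 fits without 1 array. The mast cell call held in 13 of 20 and the neutrophil call in 14. Collagen and macrophage genes changed only by fry's test for change in either direction (adjusted p = 0.0111 and 0.0483), with Cd163, a macrophage scavenger receptor, at least 3.1-fold lower and Msr1 at 1.71 ± 0.46.

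In this comparison 694 genes rose and 840 fell; 901 and 723 did when the percentile was taken over probes well above background on all arrays. The counts were 2167 and 2116 without WT sham day 42 replicate 2. No CaCl2 and sham array shared a slide. Slide as a random or fixed block ended the smooth muscle (adjusted p = 0.0755 and 0.141), matrix protease (0.0945 and 0.220), chemokine (0.0617 and 0.0893) and Fc receptor (0.0945 and 0.185) calls. The random block left 53 genes and 4 of 12 lists (lymph node, B, dendritic, T and NK cells), and the block without that array called 6034. Leaving out sham replicates 1, 2 or 3 gave 520, 623 and 778 genes, and CaCl2 replicates 2 or 3 gave 525 and 233. With the compared groups alone 7849 genes were called. Across genes the change had r = 0.291 with the deviation of the dim WT sham day 42 array from its group mates, and 0.368 over called genes.

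**Figure D2:**
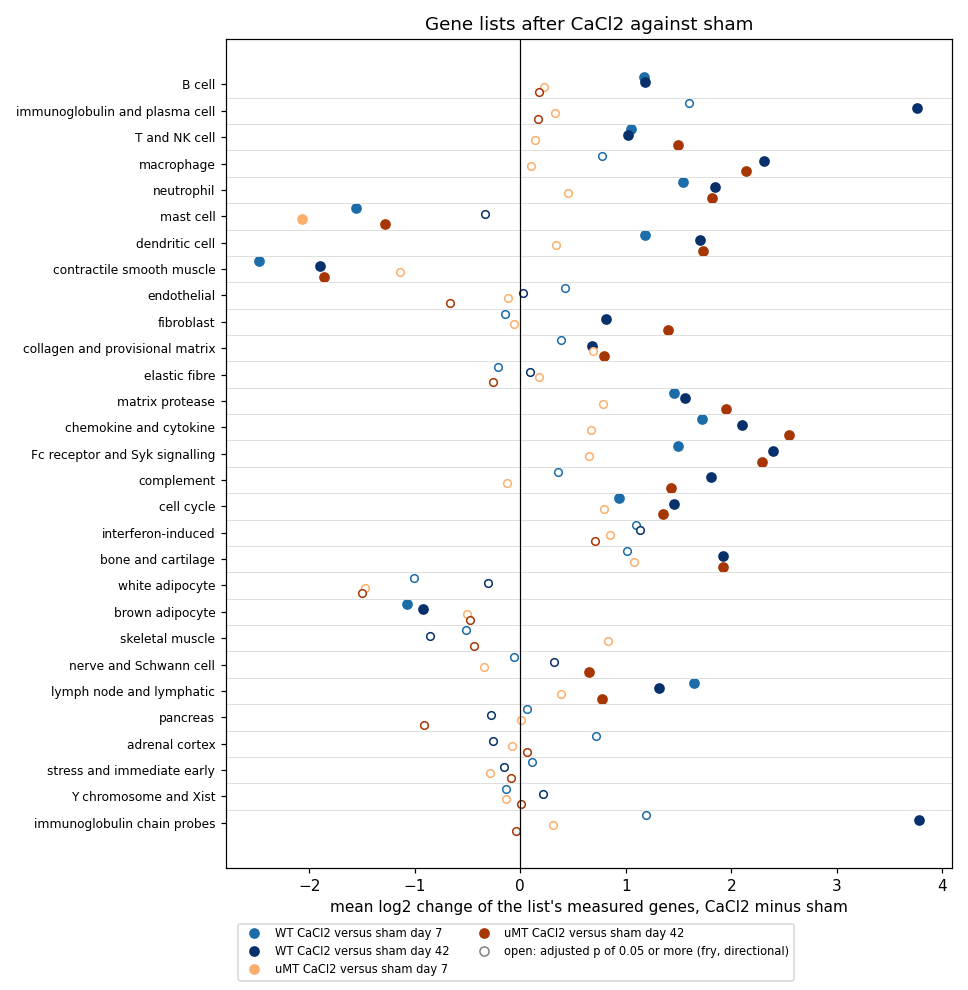
Mean log2 change of each list's measured genes, CaCl2 minus sham (x axis), for WT and uMT mice at days 7 and 42. Filled points passed fry's directional test (adjusted p below 0.05), and contractile smooth muscle genes in WT mice at day 7 lie at -2.48.

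At day 42 after CaCl2 in WT mice, antibody genes rose. Jchain rose by 9.19 ± 1.02 (adjusted p = 1.15e-05), from -3.67 ± 1.89 in sham, where 1 of 3 arrays measured it, to 5.52 ± 1.23. Spp1, which codes for the matrix protein osteopontin (probe at mm9 chromosome 5, 104868502 to 104868561), rose by 6.92 ± 1.17 (adjusted p = 7.85e-04). S100a9, a protein abundant in neutrophils, rose by 6.58 ± 1.64, the protease inhibitor Stfa3 by 6.15 ± 0.82 and the acute phase gene Saa3 by 5.71 ± 0.96. Kng1, which codes for kininogen, rose by 5.23 ± 0.58, Anxa8 by 5.09 ± 0.85 and Cfi, which codes for complement factor I, at least 9.9-fold. Mylk4, a myosin light chain kinase, fell by 4.25 ± 0.94 (adjusted p = 0.00565), as did the matrix protein gene Npnt, at -4.06 ± 0.81, and Abra, at -3.54 ± 0.83. Hhip, a hedgehog-binding protein, fell by 3.20 ± 0.86 and Klk10 by 3.19 ± 0.67. Slc22a2 fell by 3.42 ± 0.83, and Tmem200b at least 7.9-fold. Syk rose by 1.92 ± 0.46 (adjusted p = 0.00940) and the gelatinase Mmp2 by 2.94 ± 0.87 (0.0320), while Mmp9, at 0.72 ± 1.36, and Eln, at -0.94 ± 0.74, did not pass the test.

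Of the 70 immunoglobulin chain features 57 were higher and 0 lower, with a median change of 4.03 (fry adjusted p = 4.85e-05), and 69 were well above background on all 3 CaCl2 arrays but 45 on no sham array. The immunoglobulin and plasma cell list, with no heavy or light chain gene among its 4 measured genes, rose in 2 of 4, 4 adjusted over the list alone (adjusted p = 3.58e-05). Fc receptor and Syk signalling genes rose in 12 of 16 cases, 16 adjusted over the list alone (adjusted p = 4.51e-04), including Fgr (at least 7.9-fold) and Vav1 at 2.57 ± 0.50. Macrophage genes rose in 15 of 19 cases, 16 adjusted over the list alone (adjusted p = 0.00148), with Trem2, a lipid-sensing receptor, at 3.57 ± 0.67 and Csf1r, the receptor of macrophage growth factor, at 1.85 ± 0.40. Complement genes rose in 7 of 11 cases, 10 adjusted over the list alone (adjusted p = 3.58e-05), with C4b at 3.05 ± 0.30 and C3 at 2.42 ± 0.33. Chemokines rose in 9 of 22, 16 adjusted over the list alone, with Cxcl16 at 2.77 ± 0.47. Matrix proteases rose in 7 of 16 cases and fell in 1, against 11 and 2 adjusted over the list alone, with the cathepsins Ctsb at 1.42 ± 0.30 and Ctss at 3.86 ± 0.96. Bone and cartilage genes rose in 4 of 8, 5 adjusted over the list alone, with Ibsp, a bone matrix protein, at 3.44 ± 0.77 and the cartilage transcription factor Sox9 at least 2.8-fold. Each of the last 3 lists had adjusted p = 4.51e-04.

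Contractile smooth muscle genes fell in 8 of 15 cases, 13 adjusted over the list alone (adjusted p = 0.00694), with Myh11, the smooth muscle myosin heavy chain, at -3.11 ± 0.68 and its activator Myocd at -2.65 ± 0.67. Collagen genes rose in 8 of 20 and fell in 1, against 10 and 1 adjusted over the list alone (adjusted p = 0.0109), with Col3a1 at 1.41 ± 0.23, Timp1 at 2.58 ± 0.42 and Bgn, a small proteoglycan, at -1.90 ± 0.33. The lists of the cell cycle (9 of 17, 14 adjusted over the list alone; adjusted p = 0.00278), T and NK cells (7 of 16, 7; 0.0112), dendritic cells (4 of 7, 5; 4.51e-04), B cells (4 of 13, 5; 0.0102), lymph node (2 of 6, 2; 4.51e-04), neutrophils (3 of 10, 5; 0.0199) and fibroblasts (2 of 9, 3; 0.0302) were higher. Dendritic cell and fibroblast genes each held 1 lower gene as well, the second only over the list alone. Brown adipocyte genes were lower (2 of 7, 3; 0.0121), and Ccl19, a chemokine of lymph nodes, rose by 1.85 ± 0.38.

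At day 42 in WT mice 1581 genes rose and 836 fell, against 1662 and 1192 without sham replicate 2. With the compared groups alone 0 genes were called and 8 of 17 lists held; the macrophage (0.102), B cell (0.247), T and NK cell (0.0839), cell cycle (0.0973), bone (0.0839) and lymph node (0.104) calls were among those lost. Slide as a random block gave 1066 genes, and 14 of 17 lists held. Without sham replicate 2, the dim array, the collagen and fibroblast lists were not called (adjusted p = 0.124 and 0.188), and over 21 alternatives they held in 12 and 11, the neutrophil list in 15 and the brown adipocyte list in 16. Leaving out sham replicates 1 or 3, which leaves the dim array as 1 of 2 sham arrays, gave 6220 and 6106 genes, and CaCl2 replicates 2 or 3 gave 1286 and 1412.

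**Figure D3:**
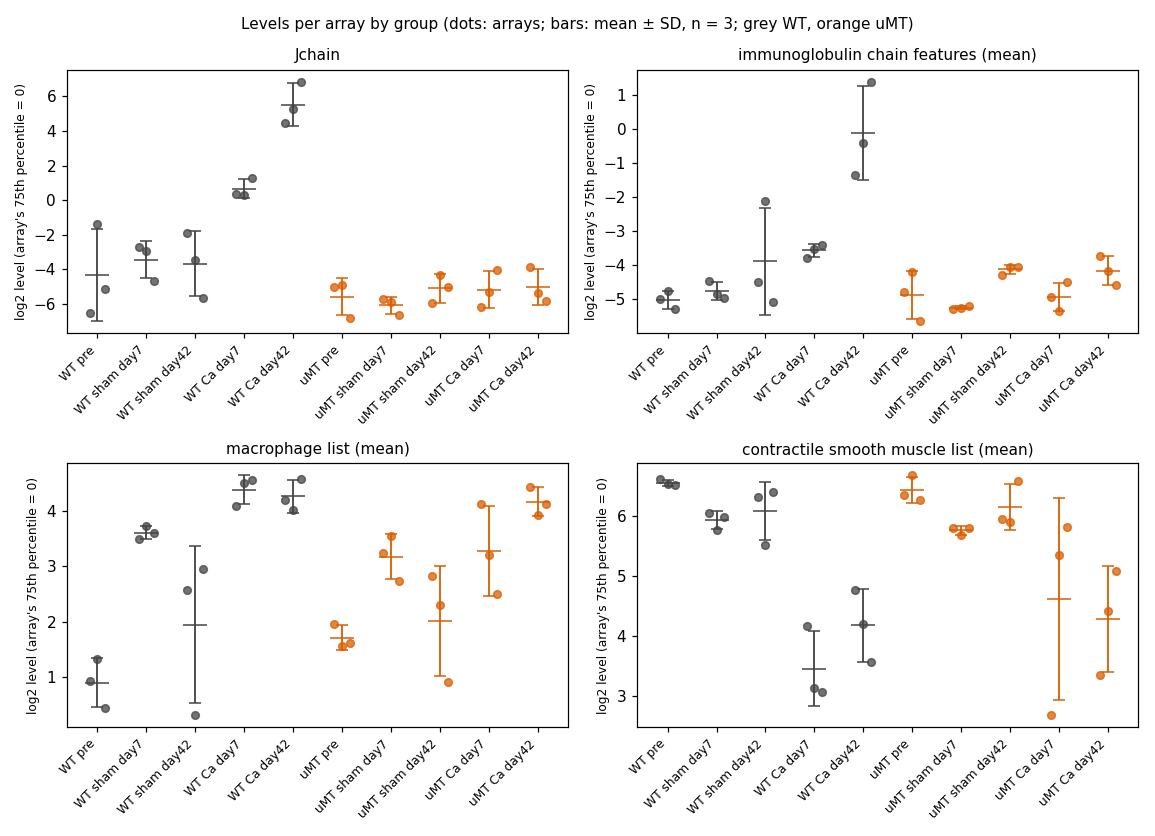
Log2 level relative to the array's 75th percentile (y axis) on each array for Jchain and for the means of the immunoglobulin features, the macrophage list and the smooth muscle list. Dots are arrays and bars the mean ± SD of 3, and Jchain in WT mice at day 42 after CaCl2 sits between 4.44 and 6.85.

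At day 7 after CaCl2 in uMT mice, Col11a1 rose by 4.18 ± 0.66 (adjusted p = 0.00601), Il1b by 3.36 ± 0.81 (0.0484) and Stfa3 by 3.35 ± 0.82. Hmox1, a haem-degrading enzyme, rose by 3.01 ± 0.73, Btk by 3.01 ± 0.66, and the collagen gene Col8a2 rose too (adjusted p = 0.0451). The protease inhibitor Spint1 and the cell cycle inhibitor locus Cdkn2a rose at least 5.4-fold and 6.3-fold. Retnla, a secreted product of alternatively activated macrophages, fell by 6.37 ± 1.13 (adjusted p = 0.0127), from 4.03 ± 0.15 to -2.34 ± 4.14. Sost fell by 3.93 ± 0.76 and Hebp1 by 2.90 ± 0.49, and the Wnt inhibitor Dkk1 at least 4.2-fold. Fcna, a ficolin of innate immunity, fell by 2.90 ± 0.67, the lectin Cd209g by 2.78 ± 0.47 and Hoxb9 at least 4.0-fold. Mast cell genes were lower (1 of 5, 3 adjusted over the list alone; fry adjusted p = 0.00679), with Cma1 at -3.47 ± 0.73. That call was lost without the filter (0.0618), with the compared groups alone (0.0822), with slide as a random block (0.974) and without sham replicate 1 (0.0635). Collagen genes changed by the test for either direction (adjusted p = 0.0307), with Col5a1 at 1.48 ± 0.35. No other list passed, smooth muscle included. Syk, at 0.53 ± 0.46 (adjusted p = 0.635), and Eln, at -0.07 ± 0.74, did not pass either.

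Here 117 genes rose and 91 fell, 1137 and 1147 without WT sham day 42 replicate 2, and 0 with slide as a random block (4086 with the block and without that array). The filter, the scaling and the arrays moved the count: 39 genes without the filter, 335 after normexp background correction, 88 after quantile normalization, and 12, 14, 17, 4, 392 and 317 without sham replicates 1 to 3 and CaCl2 replicates 1 to 3. The smooth muscle list had a mean level of 2.69 on CaCl2 replicate 1 and of 5.35 and 5.83 on replicates 2 and 3. With the compared groups alone 0 genes were called, and across genes the change had r = 0.336 with the deviation of the dim WT sham day 42 array from its group mates (0.424 over called genes).

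At day 42 after CaCl2 in uMT mice, Thbs4, a matrix thrombospondin (probe at mm9 chromosome 13, 93521565 to 93521624), rose by 7.52 ± 1.06 (adjusted p = 1.82e-04, at least 38.9-fold). Il1b rose by 6.25 ± 0.81 (adjusted p = 8.46e-05), Prg4, which codes for the joint lubricant lubricin, by 6.12 ± 0.61 and S100a9 by 6.12 ± 1.64. The chemokines Cxcl3, Ppbp and Cxcl5 rose at least 24.6-fold, 23.4-fold and 13.1-fold, and Stfa3 rose by 5.78 ± 0.82. Ciart, a repressor of the circadian clock, fell by 3.91 ± 0.69 (adjusted p = 0.00119), and Cyp2b10 by 3.72 ± 0.88. Klk11 fell by 3.40 ± 0.73, the growth factor gene Bmp6 by 3.20 ± 0.67, Sost by 3.12 ± 0.76 and Mcpt-ps1 by 3.09 ± 0.75. Syk rose by 1.93 ± 0.46 (adjusted p = 0.0123), the monocyte chemokine Ccl2 by 4.34 ± 0.84 (0.00279) and Il6 by 3.85 ± 1.07 (0.0305), while Mmp2, at 2.37 ± 0.87 (0.114), did not pass.

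Of the 70 immunoglobulin chain features, 0 passed limma's test in uMT mice at day 42 and 0 at day 7. At day 42, 45 features were well above background on no sham array and 52 on no CaCl2 array. Matrix proteases rose in 6 of 16 cases, against 11 higher and 1 lower adjusted over the list alone (fry adjusted p = 4.42e-05), with Mmp14 at 2.11 ± 0.33 and Mmp3 at 3.23 ± 0.52. Chemokines rose in 12 of 22, 15 adjusted over the list alone (adjusted p = 2.24e-04), with Ccl4 at 3.40 ± 0.62. Fc receptor and Syk signalling genes rose in 12 of 16, 14 adjusted over the list alone (adjusted p = 6.08e-04), with Fgr at 3.88 ± 0.64. Macrophage genes rose in 10 of 19, 15 adjusted over the list alone (adjusted p = 0.00162), with Cd14, the coreceptor for lipopolysaccharide, at 3.65 ± 0.59. Complement genes rose in 5 of 11, 6 adjusted over the list alone (adjusted p = 5.16e-04), with C3 at 2.49 ± 0.33 and C5ar1 at 3.11 ± 0.50. Collagen genes rose in 6 of 20, 10 adjusted over the list alone (adjusted p = 0.00138), with Timp1 at 3.48 ± 0.42. Bone and cartilage genes rose in 4 of 8 by both counts (adjusted p = 6.72e-04), with Col2a1, the main cartilage collagen, at least 7.5-fold. Smooth muscle genes fell in 5 of 15, 15 adjusted over the list alone (adjusted p = 0.00706), with Acta2, the smooth muscle actin, at -1.78 ± 0.53. The lists of dendritic cells (5 of 7, 5; 2.24e-04), fibroblasts (4 of 9, 6; 6.08e-04), T and NK cells (6 of 16, 8; 7.70e-04), the cell cycle (5 of 17, 15; 0.00519), nerve and Schwann cells (3 of 7, 3; 0.00664), neutrophils (4 of 10, 5; 0.0137) and lymph node (0 of 6, 2; 0.0236) were higher. Mast cell genes were lower (2 of 5, 3; 0.0419), and brown adipocyte genes changed in either direction (0.0399), with Dio2, a thyroid hormone deiodinase, at 3.63 ± 0.45 and Cidea, a lipid droplet protein, at -2.89 ± 0.89 (adjusted p = 0.0534).

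At day 42 in uMT mice 1075 genes rose and 398 fell, 2063 and 1431 without WT sham day 42 replicate 2. Slide as a random block left 0 genes and 0 of 16 lists, and the block without that array called 4879 genes. Over 19 alternatives the mast cell call held in 11, that of the lymph node list in 12 and that of smooth muscle in 15. With the compared groups alone 618 genes were called and 12 of 16 lists held. Without the 6 dim arrays 45 genes and 1 of 16 lists were called from 1 sham and 1 CaCl2 array, and omitting sham replicates 2 or 3 or CaCl2 replicates 1 or 2 gave 850, 496, 641 and 808.

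The genotype by treatment interaction asked whether the response to CaCl2 differed between uMT and WT mice. At day 7 limma called 0 genes (981 at an unadjusted p under 0.05, and 16 genes when only the 4 groups were fitted), and no list passed. The differences for Mmp9, at -4.06 ± 1.92, Il6, at -2.05 ± 1.51, and Syk, at -0.81 ± 0.65, did not pass the test. At day 42, 3 genes responded more strongly upward in uMT mice: Dio2 by 3.58 ± 0.63 (adjusted p = 0.0176), Faim2, an inhibitor of Fas-induced cell death, by 3.02 ± 0.55 (0.0192) and Gab2, a signalling adaptor, by 1.91 ± 0.37 (0.0358). Jchain responded less (adjusted p = 0.00796), by an amount not measured, since no uMT array of day 42 held it above background. Of the 22 lower responses, 13 were of immunoglobulin features and others of predicted genes. The immunoglobulin and plasma cell list was lower (1 of 4 genes, 2 adjusted over the list alone; fry adjusted p = 0.00750), as were the immunoglobulin features (13 of 70, 56 adjusted over the list alone; adjusted p = 0.00407). For Syk the interaction was 0.01 ± 0.65 and for Eln 0.05 ± 1.04, with adjusted p of 0.998 and 0.991.

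The 0 genes at day 7 were 47 with slide as a random block and without WT sham day 42 replicate 2, 5 without the 6 dim arrays and 3 without uMT CaCl2 replicate 1. The 25 genes at day 42 were 104 without WT sham day 42 replicate 2, 0 with slide as a random block and with only the 4 groups fitted, 70 after quantile normalization and 5 under the stricter filter. They were 51 and 4 without WT CaCl2 replicates 1 and 3, 5 and 11 without uMT sham replicates 2 and 3, and 8 and 9 without uMT CaCl2 replicates 2 and 3. The immunoglobulin and plasma cell list lost its call with the slide block, with the 4 groups alone, without the 6 dim arrays and under both other filters (adjusted p over 25 alternatives 1.83e-04 to 0.298).

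Over all genes the 2 genotypes' responses to CaCl2 had r = 0.664 at day 7 and 0.609 at day 42, across genes, which are not independent replicates. At day 7, 124 genes passed in both, 74 higher against 3.49 by chance and 50 lower against 3.29, and none moved in opposite directions. At day 42, 874 genes passed in both and 872 of them moved the same way, 734 higher against 73.0 by chance and 138 lower against 14.3. A score over the genes that responded to CaCl2 on average shifted by 1.86 in WT and 1.36 in uMT mice at day 7 (1821 genes), a difference of -0.500 (two-sided exact permutation, p = 0.385, 400 arrangements, smallest possible p 0.005). At day 42 it shifted by 1.83 and 1.64 (2639 genes), a difference of -0.185 (exact permutation p = 0.570). Leaving out 1 array moved the difference from -1.08 to -0.133 (p 0.09 to 0.82) at day 7 and from -0.600 to 0.0523, a change of sign, at day 42 (0.29 to 0.99).

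Directly compared 7 days after CaCl2, uMT mice had lower B cell genes than WT mice. Jchain was at least 21.9-fold lower (-5.83 ± 1.02, adjusted p = 0.0104), Fcmr, the receptor for IgM, at least 3.7-fold, Fcrla at least 2.6-fold and Pou2af1 at least 2.4-fold. Tnnc2, a troponin of fast skeletal muscle, was higher by 3.50 ± 0.49 (adjusted p = 0.00268), Vgll2 at least 7.5-fold, Map1b by 3.04 ± 0.53, Adcy1 at least 3.0-fold and Dgkk, a diacylglycerol kinase, by 1.88 ± 0.35. B cell genes were lower in 3 of 13 cases, 9 adjusted over the list alone (fry adjusted p = 0.00121). The lymph node (0 of 6, 1; adjusted p = 0.0227), dendritic cell (0 of 7, 1; 0.0250) and T and NK cell (0 of 16, 1; 0.0416) lists were lower and the skeletal muscle list (1 of 8, 2; 0.0250) higher. The skeletal muscle call was lost after normexp correction (0.0526), with the compared groups alone (0.286) and without WT replicates 1, 2 or 3 (0.0621, 0.0701 and 0.0945). Over 19 alternatives it held in 13, the lymph node call in 14, the dendritic cell call in 11 and the T and NK cell call in 10. Of 70 immunoglobulin features 5 were lower. Syk differed by -1.18 ± 0.46 (adjusted p = 0.311).

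At day 42 Jchain was at least 378-fold lower in uMT than in WT mice after CaCl2 (-10.55 ± 1.02, adjusted p = 3.82e-06), Pou2af1 at least 4.9-fold, Vpreb3 at least 2.8-fold and Fcmr at least 2.6-fold. Derl3, a chaperone system gene of secretory cells, was lower by 2.79 ± 0.49 and Cyp2b10 by 4.19 ± 0.88. Of 70 immunoglobulin features 50 were lower (fry adjusted p = 3.29e-05), and 52 were well above background on no uMT array. Spon2, a secreted matrix protein, was higher by 3.52 ± 0.84 (adjusted p = 0.0388), Pdzrn3 by 2.57 ± 0.65, Map1b by 2.52 ± 0.53, the neurokinin receptor gene Tacr2 by 2.42 ± 0.60 and Fbxo31 by 2.27 ± 0.58. The B cell list (3 of 13, 8 adjusted over the list alone; adjusted p = 0.00241) and the immunoglobulin and plasma cell list (2 of 4, 3; adjusted p = 1.39e-05) were lower. Mmp2, Mmp9 and Syk differed by -0.55 ± 0.87, 0.01 ± 1.36 and 0.24 ± 0.46, with adjusted p of 0.785, 0.998 and 0.822.

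These contrasts called 17 higher and 34 lower genes at day 7 and 44 and 260 at day 42, and 143 and 308, and 1086 and 2488, without WT sham day 42 replicate 2. No slide holds CaCl2 arrays of both genotypes, and slide as a random block left 0 genes and 0 lists in both (1881 and 5566 genes without that array). At day 42 the split was 225 higher and 435 lower after normexp correction and 113 and 344 after quantile normalization. The day 7 count was 1177, 14 and 10 without uMT replicates 1 to 3 and 32, 11 and 6 without WT replicates 1 to 3; at day 42 omitting WT replicates 2 or 3 gave 127 and 80, and uMT replicates 1 or 2 gave 124 and 113. With the compared groups alone 6 genes and 0 of 5 lists were called at day 7. At day 42, 2 of the 3 uMT arrays were dim, and across genes the difference had r = 0.415 with the deviation of the dim WT sham day 42 array from its group mates (-0.400 over called genes, and 0.0354 and -0.468 at day 7).

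Between day 7 and day 42 after CaCl2 in WT mice, antibody genes rose. Jchain rose by 4.86 ± 1.02 (adjusted p = 0.0208) and 39 of the 70 immunoglobulin features rose (median 3.64, fry adjusted p = 2.86e-04). Tnfrsf17, the plasma cell receptor BCMA, rose at least 4.3-fold, and the immunoglobulin and plasma cell list rose in 2 of 4 genes, 3 adjusted over the list alone (adjusted p = 5.53e-04). The list's call was lost within the slide and with the compared groups alone (0.0968 in both) and under the stricter filter (0.0765). Inmt rose by 6.21 ± 0.86, Ibsp at least 32.8-fold, Sult1e1, an oestrogen sulfotransferase, by 4.44 ± 0.84 and Duoxa2 at least 3.8-fold. Agtr2, an angiotensin II receptor, fell at least 10.9-fold and the basement membrane gene Frem1 at least 3.5-fold. Vsig8, at -4.24 ± 0.72, Spon2, at -3.68 ± 0.84, and Mest, an imprinted gene, at -3.46 ± 0.75, fell as well. Of 17 cell cycle genes 1 fell, Cdk1 at -2.01 ± 0.41, and 16 adjusted over the list alone (adjusted p = 0.00867); this call was lost within the slide (0.126), with the compared groups alone (0.140), and without day 7 replicate 3 (0.0507) or day 42 replicate 3 (0.0757). Complement and collagen genes changed by the test for either direction (adjusted p = 0.0200 and 0.0146; 3 of 11 higher and 2 of 20 lower), with C3 at 2.21 ± 0.33 and the matrix genes Cthrc1 at -3.16 ± 0.48 and Postn at -2.17 ± 0.43.

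In uMT mice over the same interval, Cxcl3 rose by 5.94 ± 0.91 (adjusted p = 0.00169), Retnla by 5.87 ± 1.13, Prg4 by 4.08 ± 0.61, and Lingo4 and Olfr553 each at least 4.8-fold. Cthrc1 fell by 4.55 ± 0.48 (adjusted p = 2.80e-05), as did Mest, at -4.35 ± 0.75, and Gdpd2, at -3.20 ± 0.40, and the tendon gene Tnmd and the kinase Nrk fell at least 2.6-fold and 2.0-fold. Elastic fibre genes fell in 3 of 10 cases, 8 adjusted over the list alone (fry adjusted p = 2.30e-04), with Mfap2 at -1.97 ± 0.38 and Mfap4 at -2.16 ± 0.43, both microfibril components. Collagen genes fell in 3 of 20, 7 adjusted over the list alone (adjusted p = 0.00695), with Postn at -2.65 ± 0.43, and the cell cycle list fell (1 of 17, 13; adjusted p = 0.00695). Nerve and Schwann cell genes rose in 2 of 7, 3 adjusted over the list alone (adjusted p = 2.30e-04). T and NK cell (1 of 16, 3; adjusted p = 0.00695), dendritic cell (1 of 7, 1; 0.00695) and chemokine genes (1 of 22, 5; 0.0323) were higher. Eln, at -2.93 ± 0.74 (adjusted p = 0.0550), did not pass. Within their slide all 7 lists lost their calls, at an adjusted p of 0.0679 for elastic fibre, collagen and dendritic cell genes, and over 21 alternatives the chemokine call held in 11. Of the 3 day 42 arrays 2 were dim, and across genes the change had r = 0.492 with the deviation of the dim WT sham day 42 array from its group mates (0.245 over called genes).

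Each line's arrays of both days lay on 1 slide. The counts were 106 higher and 22 lower in WT mice and 127 and 99 in uMT mice, and 170 and 56, and 900 and 1025, without WT sham day 42 replicate 2. Normexp correction gave 134 and 57 in WT mice; in uMT mice the split was 96 and 119 after quantile normalization, 90 and 118 with the authors' values and 147 and 67 with the percentile over all-array probes. Slide as a random block gave 243 and 1117 genes, and fitting the uMT slide alone 3. In WT mice the change had, over called genes, r = 0.414 with the deviation of the dim WT sham day 42 array from its group mates (0.102 over all genes). Without WT day 7 replicates 1, 2 or 3 or day 42 replicate 3 the WT count was 79, 77, 72 and 54; without uMT day 7 replicates 1 or 2 or day 42 replicates 1 or 2 the uMT count was 451, 117, 90 and 112.

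The sham operation was compared with unoperated aorta to measure what surgery and time did without CaCl2. At day 7 in WT mice the acute phase gene Saa3 rose at least 191-fold (9.62 ± 0.96, adjusted p = 4.88e-06), Atp6v0d2, a proton pump subunit of osteoclasts and macrophages, at least 102-fold, Mmp12, the macrophage elastase, at least 47.0-fold and Syngr1 at least 44.5-fold. Spp1 rose by 7.36 ± 1.17 and Syk by 1.88 ± 0.46 (adjusted p = 0.0252). The clock gene Bhlhe41 fell by 1.76 ± 0.28, while Ptprq, Lrrc26 and Crb2 fell at least 2.2-fold, 2.0-fold and 1.7-fold. Cell cycle genes rose in 13 of 17 cases, 16 adjusted over the list alone (fry adjusted p = 1.95e-04), with Top2a, a topoisomerase of dividing cells, at 3.64 ± 0.68. Macrophage genes rose in 11 of 19, against 15 higher and 1 lower adjusted over the list alone (adjusted p = 9.69e-04), with Trem2 at 5.26 ± 0.67, and Fc receptor and Syk signalling genes in 8 of 16, 13 adjusted over the list alone (adjusted p = 0.00129), with Fcgr4 at 4.63 ± 0.54. The lists of matrix proteases (3 of 16, 7; 1.95e-04), dendritic cells (2 of 7, 4; 0.00129), chemokines (6 of 22, 12; 0.00132), complement (4 of 11, 6; 0.00233), T and NK cells (1 of 16, 2; 0.0198), neutrophils (1 of 10, 4; 0.0361) and B cells (2 of 13, 4; 0.0468) were higher. Collagen genes changed by the test for either direction (adjusted p = 2.72e-05), with Cthrc1, a collagen triple helix protein, at 5.05 ± 0.48.

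At day 42 after sham in WT mice Fpr1, a neutrophil receptor for bacterial peptides, rose at least 5.8-fold, the class II antigen gene H2-Aa by 2.75 ± 0.36 (adjusted p = 0.00192), Ms4a4a by 2.40 ± 0.50, C3 by 1.80 ± 0.33 and Efemp1 by 1.75 ± 0.27. T and NK cell (0 of 16, 10 adjusted over the list alone; fry adjusted p = 0.00721), B cell (0 of 13, 6; 0.0109) and dendritic cell lists (0 of 7, 3; 0.0109) were higher, and chemokines changed by the test for either direction (adjusted p = 0.0216), with Ccl4 at least 4.1-fold higher.

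In uMT mice 7 days after sham Saa3 rose at least 116-fold (8.83 ± 0.96, adjusted p = 2.45e-05), Spp1 at least 62.2-fold, Atp6v0d2 at least 30.4-fold, Mmp12 at least 11.5-fold and Cthrc1 by 5.26 ± 0.48. Eln rose by 2.97 ± 0.74 (adjusted p = 0.0324). Cyp1a1, a xenobiotic-metabolising enzyme, fell by 3.52 ± 0.87. Krtap4-1, at -2.89 ± 0.55, the histone gene H2ac21, at -2.56 ± 0.60, Abca8a, at -2.54 ± 0.58, and the eosinophil chemokine Ccl24, at -2.52 ± 0.60, fell too. Cell cycle genes rose in 14 of 17 cases, 16 adjusted over the list alone (fry adjusted p = 1.31e-04), with Ccna2, a cyclin, at 3.81 ± 0.56. Dendritic cell (3 of 7, 4; adjusted p = 0.0108), matrix protease (2 of 16, 6; 0.0108) and Y chromosome and Xist lists (1 of 4, 1; 0.0259) were higher, the last through Ddx3y (adjusted p = 0.0309). All 3 calls were lost within slide 4 (0.277, 0.164 and 0.277), and the protease call also without pre replicate 2 (0.0541) or sham replicate 1 (0.0511), where the dendritic cell call was lost too. Collagen and macrophage genes changed by the test for either direction (adjusted p = 2.29e-06 and 0.0475), with Col3a1 at 0.85 ± 0.23 and Clec4d at 5.12 ± 0.86.

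At day 42 after sham in uMT mice Atp6v0d2, Mmp12 and Stra6l rose at least 26.2-fold, 17.6-fold and 6.6-fold. Clec4d, a lectin of myeloid cells, rose by 5.38 ± 0.86 and the integrin gene Itgax by 4.98 ± 0.84 (adjusted p = 0.00143). Ifitm6 fell by 3.67 ± 0.76, Cd163 at least 2.6-fold, Glt8d2 by 3.63 ± 0.69, Fcna by 3.57 ± 0.67 and Hsd11b1, which activates glucocorticoids, by 3.52 ± 0.50. Fibroblast genes fell in 7 of 9 cases, 8 adjusted over the list alone (fry adjusted p = 5.68e-04), with Clec3b at -2.26 ± 0.42 and the receptor Pdgfra at -1.52 ± 0.36. This call was lost within slide 4 (0.104) and with the compared groups alone (0.158). Dendritic cell genes rose in 3 of 7, against 3 higher and 1 lower adjusted over the list alone (adjusted p = 0.0446). Macrophage genes changed by the test for either direction (adjusted p = 6.49e-04), 5 higher and 4 lower of 19, with a mean of 0.31, a median of -0.48 and a directional test pointing down. Collagen genes changed in the same sense (adjusted p = 0.0482), with Bgn at -1.27 ± 0.33. Beside these groups, the arrays of uMT sham day 42 gave 46.8% to 54.3% of probes well above background, and 1 of the uMT pre arrays 43.6%, and across genes the change had r = 0.567 with the deviation of the dim WT sham day 42 array from its group mates.

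**Figure D4:**
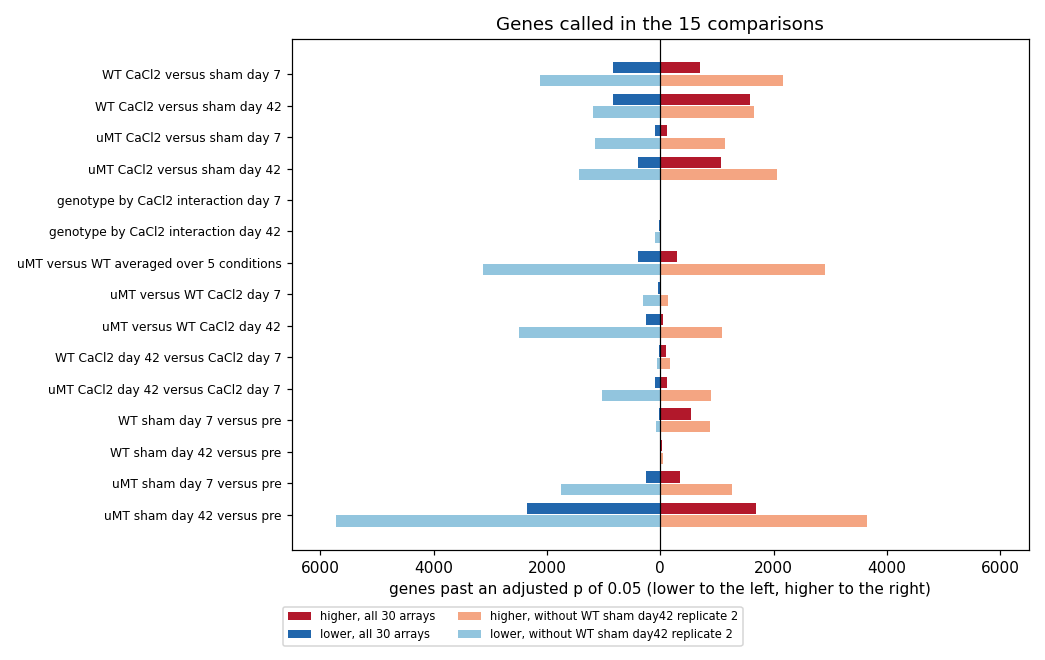
Genes past an adjusted p of 0.05 (x axis, lower to the left and higher to the right) in each of the 15 comparisons, with all 30 arrays and without WT sham day 42 replicate 2. The longest pair of bars with all arrays belongs to uMT sham day 42 against pre, with 1697 higher and 2353 lower genes.

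Endothelial genes (12 measured), white adipocyte genes (11), stress and immediate early genes (9), adrenal cortex genes (3) and pancreas genes (2) passed in none of the 15 comparisons. Their lowest fry adjusted p were 0.127, 0.227, 0.0872, 0.225 and 0.0622, and among endothelial genes 2 fell after CaCl2 at day 42 in uMT mice.

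The 4 sham comparisons called 534 higher and 17 lower genes in WT mice at day 7, 39 and 0 at day 42, 347 and 245 in uMT mice at day 7, and 1697 and 2353 at day 42. Without WT sham day 42 replicate 2 they called 880 and 75, 46 and 3, 1266 and 1744, and 3655 and 5726. With arrays of 1 slide alone the counts were 1939, 899, 9 and 1416, the second from 1 sham array, with the compared groups alone 1939, 0, 353 and 1789, and with slide as a random block WT day 7 gave 928 and uMT day 7 962 genes. Scaling moved the split: in uMT mice 249 and 77 at day 7 and 1610 and 1296 at day 42 after quantile normalization, 242 and 75 and 1614 and 1290 with the authors' values, and 613 and 156 and 2996 and 1134 with the percentile over all-array probes. For WT day 42 the split was 4 and 2 after quantile normalization and 7 and 2 with the authors' values, where its 3 lists also lost their calls. Over 21 alternatives the B cell call held in 9 for WT day 7 and 12 for WT day 42, the dendritic cell call in 15 for WT day 42 and 11 for uMT day 42, the Y chromosome and Xist call in 12 for uMT day 7, and the neutrophil and T and NK cell calls in 14 and 16 for WT day 7. Leaving out 1 array in turn gave 295, 364 and 310 genes for WT day 7 without pre replicates 1 to 3 and 307, 276 and 360 without sham replicates 1 to 3. For WT day 42 the counts were 8, 24 and 16 without pre replicates 1 to 3, and 5044 and 6658 without sham replicates 1 and 3. For uMT day 7 they were 136, 76 and 1509 without pre replicates 1 to 3 and 216, 60 and 151 without sham replicates 1 to 3. For uMT day 42 they were 1138 and 2234 without pre replicates 1 and 2, 796 and 2385 without sham replicates 2 and 3, and 246 genes without the 6 dim arrays.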

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

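The tests of lymph node tissue and of cross-hybridisation below, and the list of immunoglobulin features, were chosen after the result was seen; the test without the dim array and the splits of the arrays were planned. By a test of the difference itself, the day 42 responses to CaCl2 of uMT and WT mice differed in 25 genes. This brought these results forward. Jchain differed by -9.12 ± 1.44 (log2 ± SE), Dio2 by 3.58 ± 0.63, Faim2 by 3.02 ± 0.55 and Gab2 by 1.91 ± 0.37. The immunoglobulin and plasma cell list differed by a mean of -3.59 and the 70 immunoglobulin features by -3.81. These sizes and that of Jchain rest on uMT values below background, with 45 and 52 of 70 features, and Jchain, well above it on no uMT sham or CaCl2 array. Dio2 rose by 3.63 ± 0.45 after CaCl2 in uMT mice, and its 0.06 ± 0.45 in WT mice did not pass. Of 100 drawn exchanges of genotype labels, 18 gave as many genes as the 25, with 10011 the highest other, so chance is not excluded for the count. A split with 10011 genes points to a structure of the samples: it put the 3 dim sham arrays (WT replicate 2, uMT replicates 2 and 3) on one side and the 2 dim CaCl2 arrays on the other. With only the 4 groups fitted and with slide as a random block the count was 0, and with the block 162 when WT sham replicate 2 was also left out. Left out in turn, WT sham replicate 2 gave 104 genes, WT CaCl2 replicates 1 and 3 gave 51 and 4, uMT sham replicates 2 and 3 gave 5 and 11, and uMT CaCl2 replicates 2 and 3 gave 8 and 9. At day 7 the same test by limma gave 0 genes (981 at an unadjusted p under 0.05), and all 100 exchanges gave as many, with 0 the highest other; a count of 0 fixes that outcome, so the exchanges test nothing there.

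The immunoglobulin features made up 13 of the 25 genes, and 57 of 70 rose after CaCl2 in WT mice at day 42 and 0 in uMT mice. Lymph node tissue taken with the aorta would bring B cell, T cell and lymph node genes: from day 7 to day 42, on 1 slide, their median rose by 0.33 (35 genes, quartiles -0.04 to 0.49) against 3.64 for the immunoglobulin features (2.82 to 4.30), which argues against such tissue for this part of the rise. Cross-hybridisation among chains of similar sequence would leave Jchain, which shares none, unchanged, and it rose by 9.19; without the dim WT sham array the median rise over sham was 4.74 in place of 4.03, so neither is the whole cause. Against sham the same 35 genes rose by a median of 1.05 at day 42 (quartiles 0.11 to 1.92) and 1.05 at day 7, where the features rose by 1.06, so lymph node tissue stays open for the part present by day 7. A gain of antibody-producing cells in WT aorta after day 7 may be behind the rest, a hypothesis that arose from these data and was not itself tested. Tissue that holds plasma cells without other lymph node cells was not tested either.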

How the results depend on the processing

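The counts moved by over 1.5 times are given here by setting, as genes past the threshold in a comparison or as comparisons, of 15, in which a list passed; where no cause is named, the cause was not tested. By construction, fits of fewer arrays have fewer degrees of freedom and filters change the number of tests. The main counts were 1534 and 2417 (WT CaCl2 against sham, days 7 and 42), 208 and 1473 (uMT), 0 and 25 (response difference), 692 (genotype average), 51 and 304 (genotypes after CaCl2), 128 and 226 (WT and uMT days), 551 and 39 (WT sham against pre) and 592 and 4050 (uMT sham).

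Under normexp with quantile normalization the counts were 335 for uMT CaCl2 against sham day 7, 41 for response difference day 42, 660 for genotypes after CaCl2 day 42, 293 for WT sham day 7, 2 for WT sham day 42 and 351 for uMT sham day 7. Among lists, these moved: T cell 4, collagen 5, elastic fibre 2, interferon-induced 2 and skeletal muscle 0. Under quantile normalization the counts were 88 for uMT CaCl2 against sham day 7, 70 for response difference day 42, 30 for genotypes after CaCl2 day 7, 457 for genotypes after CaCl2 day 42, 328 for WT sham day 7, 6 for WT sham day 42 and 326 for uMT sham day 7. For lists the counts were dendritic cell 4, elastic fibre 2, interferon-induced 0 and pancreas 1. With the authors' matrix the counts were 89 for uMT CaCl2 against sham day 7, 62 for response difference day 42, 30 for genotypes after CaCl2 day 7, 326 for WT sham day 7, 9 for WT sham day 42 and 317 for uMT sham day 7. The lists moved as under quantile normalization. With no filter on dim probes the counts were 39 for uMT CaCl2 against sham day 7, 335 for genotype average, 22 for genotypes after CaCl2 day 7, 169 for genotypes after CaCl2 day 42, 276 for uMT sham day 7 and 2646 for uMT sham day 42. For lists the counts were neutrophil 2 and mast cell 1.

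With probes well above background on at least 15 arrays the counts were 5 for response difference day 42, 16 for genotypes after CaCl2 day 7, 131 for genotypes after CaCl2 day 42, 40 for WT days and 21 for WT sham day 42. Among lists, these moved: plasma cell 3, interferon-induced 0 and lymph node 2. With the mean of a gene's probes WT sham day 42 had 75. For lists the counts were elastic fibre 2 and interferon-induced 2. With the compared groups alone the counts were 7849 for WT CaCl2 against sham day 7, 0 for WT CaCl2 against sham day 42, 0 for uMT CaCl2 against sham day 7, 618 for uMT CaCl2 against sham day 42, 16 for response difference day 7, 0 for response difference day 42, 6 for genotypes after CaCl2 day 7, 3 for uMT days, 1939 for WT sham day 7, 0 for WT sham day 42, 353 for uMT sham day 7 and 1789 for uMT sham day 42. With the replicate number as a block uMT CaCl2 against sham day 7 had 110.

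With slide as a random block the counts were 53 for WT CaCl2 against sham day 7, 1066 for WT CaCl2 against sham day 42, 0 for uMT CaCl2 against sham day 7, 0 for uMT CaCl2 against sham day 42, 0 for response difference day 42, 2 for genotype average, 0 for genotypes after CaCl2 day 7, 0 for genotypes after CaCl2 day 42, 243 for WT days, 1117 for uMT days, 928 for WT sham day 7 and 962 for uMT sham day 7. Among lists, these moved: B cell 4, plasma cell 2, neutrophil 2, mast cell 0, smooth muscle 1, endothelial 1, elastic fibre 2, matrix protease 3, Fc receptor 2, bone 1, brown adipocyte 0, skeletal muscle 0, nerve 1 and lymph node 2. With slide as a fixed block the counts were 77 for WT CaCl2 against sham day 7, 957 for WT CaCl2 against sham day 42, 208 for WT days, 1635 for uMT days, 912 for WT sham day 7, 20 for WT sham day 42 and 7107 for uMT sham day 42. Within slide 1 the counts were 1939 for WT sham day 7 and 899 for WT sham day 42. Within slide 4 uMT sham had 9 at day 7 and 1416 at day 42, and within slide 5 uMT days had 3.

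In the fit of all groups without WT sham day 42 replicate 2 the counts were 4283 for WT CaCl2 against sham day 7, 2284 for uMT CaCl2 against sham day 7, 3494 for uMT CaCl2 against sham day 42, 104 for response difference day 42, 6036 for genotype average, 451 for genotypes after CaCl2 day 7, 3574 for genotypes after CaCl2 day 42, 226 for WT days, 1925 for uMT days, 955 for WT sham day 7, 3010 for uMT sham day 7 and 9381 for uMT sham day 42. Among lists, these moved: macrophage 6, elastic fibre 3, complement 9, interferon-induced 2, pancreas 1 and adrenal cortex 1. Without the 6 dim arrays the counts were 5556 for WT CaCl2 against sham day 7, 4019 for WT CaCl2 against sham day 42, 3959 for uMT CaCl2 against sham day 7, 45 for uMT CaCl2 against sham day 42, 5 for response difference day 7, 52 for response difference day 42, 247 for genotype average, 1089 for genotypes after CaCl2 day 7, 252 for WT days, 1133 for WT sham day 7, 138 for WT sham day 42 and 246 for uMT sham day 42. For lists the counts were plasma cell 3, mast cell 1, fibroblast 6, elastic fibre 3, matrix protease 3, complement 8, cell cycle 4, bone 1, nerve 5, adrenal cortex 2, stress 2 and Y chromosome 0. With the random slide block and without WT sham day 42 replicate 2 the counts were 6034 for WT CaCl2 against sham day 7, 4086 for uMT CaCl2 against sham day 7, 4879 for uMT CaCl2 against sham day 42, 47 for response difference day 7, 162 for response difference day 42, 10631 for genotype average, 1881 for genotypes after CaCl2 day 7, 5566 for genotypes after CaCl2 day 42, 226 for WT days, 1880 for uMT days, 945 for WT sham day 7, 3168 for uMT sham day 7 and 9551 for uMT sham day 42. Among lists, these moved: macrophage 5, elastic fibre 3, complement 9, interferon-induced 4, pancreas 2 and adrenal cortex 3. With the percentile over probes bright on all arrays the lists that moved were collagen 6, elastic fibre 2, complement 6, interferon-induced 2 and Y chromosome 2.

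Leaving out 1 array at a time, with 2 arrays left in its group, gave from the lowest to the highest 233 to 1165 and 1286 to 6220 genes for WT CaCl2 against sham at days 7 and 42, and 4 to 392 and 496 to 1684 for uMT mice. The ranges were 0 to 3 and 4 to 104 for the response difference, 346 to 6036 for the genotype average, and 6 to 1177 and 80 to 259 for the genotypes after CaCl2. They were 54 to 127 and 90 to 451 for the days in WT and uMT mice, 276 to 364 and 8 to 6658 for WT sham, and 60 to 1509 and 796 to 4537 for uMT sham. The genotype difference in response score ranged from -1.08 to -0.133 at day 7 and from -0.600 to 0.0523 at day 42, and none of these fits called it (lowest permutation p = 0.0900 and 0.290). Without the 6 dim arrays, which leaves 1 uMT sham and 1 uMT CaCl2 array, the day 42 difference was -0.451. Its 12 arrangements were too few to call it.

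A list is counted as turned when its directional test changed direction and either fit called it. The plasma cell list in the uMT days had a mean of -2.02 (adjusted p = 0.00551) with probes bright on 15 arrays, from 0.60. The mast cell list in WT CaCl2 against sham at day 7 had -0.119 (adjusted p = 0.830) with the fixed slide block, with the test turned upward. The endothelial list in WT sham at day 42 had 0.976 within slide 1 (adjusted p = 0.00797). The adrenal cortex list in WT CaCl2 against sham at day 42 had 0.833 (adjusted p = 0.0244) without WT sham day 42 replicate 2, alone or in the fit of all groups, 0.833 (adjusted p = 0.0131) without the 6 dim arrays and 0.854 (adjusted p = 0.0174) with the slide block added. Leaving out 1 array took it from -0.904 to 0.833, with -0.260 in all arrays. Arsk in the genotype average had -0.95 (adjusted p = 7.07e-06) as the mean of its probes, which are 2 with opposite signs.

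Of 1870 values of 375 named genes (440 main calls), the number keeping direction and side of the threshold was 1723 under normexp (88 lost and 59 gained the call), 1773 under quantile normalization (70 and 27), 1773 with the authors' matrix (74 and 23), 1787 with no filter (83 and 0) and 1826 with the mean of probes (29 and 14). It was 1840 with the replicate block (27 and 3), 1596 with the random slide block (224 and 50), 1655 without WT sham day 42 replicate 2 (15 and 200), 1588 without the dim arrays (154 and 128), 1822 with the other percentile (19 and 29) and 1559 with the slide block and without that array (10 and 301). It was 1607 of 1628 on 15 arrays (16 and 5), 1414 of 1747 with the compared groups alone (222 and 111), 849 of 1004 with the fixed slide block (98 and 57), and 197 of 247, 214 of 254, 195 of 246 and 104 of 127 within slides 1, 3, 4 and 5 (4, 30, 47 and 23 lost, 46, 10, 4 and 0 gained). Leaving out 1 array kept 14448 of 15582 (869 lost, 265 gained). Of 420 list results (85 main calls), 404 held under normexp, quantile normalization, the matrix and the other percentile, 408 with no filter or on 15 arrays, 415 with the mean of probes and 416 with the replicate block. The slide block kept 372 (39 lost and 9 gained), and 385 without WT sham day 42 replicate 2 (3 and 31); the fit of all groups without that array kept 394 (4 and 21) and that without the dim arrays 364 (28 and 27). The compared groups alone kept 331 of 392, the fixed slide block 201 of 224, slides 1, 3, 4 and 5 kept 39, 47 and 51 of 56 and 21 of 28, and leaving out 1 array 3370 of 3528. Values of any sign called in neither fit count as kept.

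Same-numbered arrays had residual correlations over 0.1 in 0 to 2 of 3 pairs and in no comparison did every array correlate best with its own number, so the number does not pair them, and the replicate block moved no other count by over 1.5 times. The fixed slide block cannot be fitted for uMT CaCl2 against sham, the response differences or the genotype comparisons, and was not run there; the random slide block gave no genes for the day 7 response score and so no value. The correlation within slide was 0.782, and -0.0687 without WT sham day 42 replicate 2, so the random block rested on that array. Where a single array stood in a group (uMT sham and CaCl2 at day 42 without the dim arrays, WT sham day 42 within slides 1 and 3), it is assumed to vary like the other groups. A change between values below background on both sides cannot be seen.

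The median change of all genes was beyond 0.1 (log2) in some fits with another scaling or filter. Under quantile normalization it was 0.104 for WT CaCl2 against sham at day 42, -0.153 for the response difference at day 42 and -0.150 for WT sham at day 42, and 0.106, -0.156 and -0.151 with the authors' matrix. With no filter it ran from -0.309 (WT CaCl2 against sham at day 42) to 0.461 (WT sham at day 42). With the percentile over probes bright on all arrays it ran from -0.127 (response difference at day 42) to 0.263 (uMT sham at day 42). On 15 arrays it was -0.106 for the response difference at day 42, and without the dim arrays -0.117 for uMT sham at day 42.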

Other observations

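The tests of signal quality, slides, GC content and strain DNA in this part were chosen after the results were seen; the splits of the arrays were planned. Tests of gene positions aside, p values measure spread between these samples, 1 array each.

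In uMT mice 4050 genes differed between sham day 42 and pre, against 39 in WT mice, a contrast that rests on single arrays: the WT count was 8, 24 and 16 without pre replicates 1 to 3 and 5044 and 6658 without sham replicates 1 and 3, the uMT count 1138 and 2234 without pre replicates 1 and 2 and 796 and 2385 without sham replicates 2 and 3, and without the 6 dim arrays they were 138 and 246 (WT and uMT). Probe GC content is argued against (r = 0.0630 across genes). A shared axis of RNA or signal quality may explain part: the uMT change followed, across genes, the deviation of WT sham day 42 replicate 2 from its group mates, an array in neither group, with r = 0.567 over all genes and 0.714 over called genes, against -0.125 for the day 7 sham change of uMT mice. A slide effect stays open, with 1 WT sham array on the WT pre slide. The uMT count was 1416 within slide 4 and rose with the fixed slide block, where the WT count fell. Time since sham surgery stays open, untested, with Itgax, Mmp12 and Atp6v0d2 higher.

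Outside the immunoglobulin features, 59 genes differed by 2-fold or more between uMT and WT mice with 1 sign in all 5 conditions, Jchain, Ms4a1 and Ly6d among them. Slide or scan batch stays open, as genotypes share 1 slide. Its uMT pre array differed from its 7 sham or CaCl2 WT arrays by a median of 0.81 in the genotype's direction. Of 55 genes chosen without it 45 had that sign (median size 1.33), but treatment differed as well. DNA of another strain around some genes in 1 colony could also account for part. Chromosome 13 held 9 of the 59 genes against 2.47 by chance (smallest adjusted p over chromosomes 0.0144, 1-sided Fisher's exact test), but over all 649 called genes with a position, tested first, the smallest was 0.0889, on chromosome 12. The 9 genes start between 75986983 and 120124394 (mm9) and include Arsk, Map1b, Esm1 and Nnt, and Nnt is known to carry a deletion in the C57BL/6J substrain.

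The 2 Arsk probes, 1.77 and -3.68, and the 2 Slc35e2 probes, 1.47 and -0.65, were called in opposite directions between uMT and WT mice, so a single value does not describe these genes. Of the 59 genes 24 had another of them within 5 Mb, against a median of 15 by chance (permutation p = 0.0268, 10000 random draws), and families of neighbouring genes raise such a count.

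Other splits of the same arrays were fitted for each comparison. For uMT against WT mice over all conditions, 2 of 100 gave as many genes as the 692, the real one included, with 4089 the highest other. This share is under 0.05 but cannot tell genotype from slide. The split with 4089 points to a structure of the samples, with all 6 dim arrays on one side. With slide as a random block the count was 2, and 10631 also without WT sham day 42 replicate 2. The 692 became 6036 without that array and 1209 without uMT sham day 42 replicate 1. It was 384 and 375 without WT pre replicates 1 and 2, 414 and 427 without WT sham day 7 replicates 2 and 3, 346 without WT CaCl2 day 7 replicate 3 and 416 without WT CaCl2 day 42 replicate 3. Without uMT arrays it was 438 (pre replicate 2), 433 and 385 (sham day 7 replicates 2 and 3), 399 and 418 (sham day 42 replicates 2 and 3), 427 (CaCl2 day 7 replicate 3) and 389 (CaCl2 day 42 replicate 2).

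The 12 comparisons of 3 arrays with 3 have 10 splits each, too few for a share under 0.05. With the real count first and the highest other second, they gave 1534 and 0 for WT CaCl2 against sham at day 7 and 208 and 0 and 1473 and 0 for uMT mice at days 7 and 42. They gave 304 and 0 for the genotypes after CaCl2 at day 42, 128 and 0 for the days after CaCl2 in WT mice, 551 and 3 for WT sham at day 7, 39 and 1 at day 42, and 592 and 0 and 4050 and 18 for uMT sham, and in each of these 9 only 1 split, the real one, gave as many. In 3 comparisons 2 splits did: 2417 and 4041 for WT CaCl2 against sham at day 42, 51 and 435 for the genotypes after CaCl2 at day 7, and 226 and 328 for the days in uMT mice. The first of these put sham replicates 1 and 3 with CaCl2 replicate 3, the second set WT replicate 1 with uMT replicates 2 and 3, and the third put day 7 replicate 1 with day 42 replicates 1 and 2, the 2 dim arrays of that comparison. The random slide block gave 1117 for the last, and 1880 when WT sham day 42 replicate 2 was also left out. The first followed the first principal component, with the dim array, alone on slide 2, beside CaCl2 replicates 1 and 2 (1066 with the slide block). The second followed the response score of the arrays. Both point to a structure of the samples.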
